A study of Mus musculus with 8 samples.

How the data were processed

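Total RNA of 8 mouse gastrocnemius muscles, 4 control and 4 GR_KO, was hybridised to Affymetrix arrays after biotin labelling. The deposited values are signal intensities on a linear scale, made by the authors with MAS5 per the submitters' processing notes. The version and scaling target of MAS5 are not given in the sources used here. All values in the table were whole numbers, and the mean of each array after leaving out 2% of probe sets at each end was 99.96, so the arrays had been scaled to a common mean before deposit. Of the 45101 probe sets, 64 were control probe sets and were left out of the tests. Among the other 45037, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none. A RefSeq table matched 34741 of the single-gene probe sets by gene identifier, and 204 kept the annotation's symbol.

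The log2 of each signal was used with no pseudocount and no further normalization, and values of 0 were set to the smallest positive value of the array, which applied to 1 value among the probe sets tested. Each of the 18193 genes was represented by its brightest single-gene probe set over all 8 arrays. Of these genes 9010 had more than 1 probe set, and probe sets of a gene could disagree, as those of Nr3c1 did. Genes were tested when the mean log2 signal was above the median of all probe sets, a signal of 19.4, which kept 11062 genes and left 7131 out as dim. MAS5 signals near that level are noisy, so fold changes of dim genes are less certain. Mstn was not analysed here.

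Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Figures and file handling used Python 3.11.15. The fit held the group alone. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical in part. No 2 arrays held identical values. Fold changes are GR_KO against control, taken from mean log2 signals, so they can differ slightly from ratios of the mean signals, and their errors are standard errors of the fit. Signals are given as mean ± SD of 4 arrays.

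A set of 33 gene lists was fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The lists covered glucocorticoid-induced genes, muscle atrophy genes, other pathways of muscle and markers of other cell types in a whole muscle, and some genes stood in more than 1 list. Each list with at least 5 tested members was tested with camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Beside it stand camera with an estimated correlation, fry in its directional and mixed forms, and an exact permutation test of the list score over all 70 arrangements of 4 against 4, two-sided, whose smallest p is 0.0286. After adjustment over the lists 0 passed the exact test (smallest adjusted p = 0.471).

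The rule for named genes took Nr3c1 on every array and then, among genes past the threshold with non-overlapping groups, up to 12 with the highest and 12 with the lowest fold change. Where fewer than 6 existed in a direction, the genes of that direction with the smallest p filled up to 6 and are given as not past the threshold. It also took up to 4 members of each list with the smallest p, and Fkbp5, Tsc22d3, Ddit4, Mstn, Foxo3, Fbxo32 and Trim63 whatever their p. Names of predicted transcripts were passed over.

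The steps were tested on simulated data drawn from the means and spreads of the 11062 genes, with 200 genes changed in each of 20 runs. The gene test recovered 13.8% of genes changed by 0.58 on the log2 scale, 61.8% at 1.00, 90.1% at 1.50 and 96.0% at 2.00, and 5.04% of its calls were false. A list shifted by -0.30 was called in 20 of 20 runs, and 0.484% of lists sharing no gene with it were called. These simulated genes varied independently, unlike genes on real arrays.

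Alternatives were quantile normalization and median centring, and pseudocounts of 2 and 6 (the 10th and 25th percentiles of all signals). No filter and a filter at the 70th percentile were also used. A gene's probe sets were averaged, or every probe set above the signal filter was tested. Further fits used eBayes without trend or with a robust prior, array weights, a replicate block or other thresholds, or left out each array. A fit with the spike-in signal as covariate was added after the spike-in signals had been seen.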

Results

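Gene expression was measured in mouse gastrocnemius, the large calf muscle, with 1 Affymetrix array per sample. The 8 samples fell into 2 groups of 4. The control samples were labelled as wild type, and the GR_KO samples as knockouts of the glucocorticoid receptor. The receptor is a hormone-activated transcription factor encoded by Nr3c1. The comparison of the 2 groups asks which transcripts of the muscle differ when the receptor gene is disrupted. The table held MAS5 signals for 45101 probe sets, and the number of arrays limits the precision of every value below. The median signal per array lay between 18 and 26, and the trimmed mean signal lay between 99.960 and 99.964 on all 8 arrays.

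The targeted gene was lower on the GR_KO arrays. The Nr3c1 probe set 1460303_at had a signal of 336 ± 34.7 in control muscle and 95.8 ± 26.7 in GR_KO muscle (mean ± SD, n = 4 per group), a 3.59-fold difference. Its 4 control signals were 377, 307, 307 and 352, and its 4 GR_KO signals were 134, 79, 76 and 94. Probe set 1457635_s_at was 3.88-fold lower, at 25.8% of the control level. In limma over all probe sets, their log2 fold changes were -1.84 ± 0.19 and -1.96 ± 0.25 (SE, unadjusted p = 4.16e-06 and 2.27e-05). In a separate limma fit of the 22518 probe sets above the signal filter, their adjusted p-values were 0.0240 and 0.0354. Adjusted p-values without the filter are not given here.

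The other Nr3c1 probe sets moved less or were dim. The brightest one over the 8 arrays, 1421867_at, stood for the gene in the gene test and had a log2 fold change of -1.07 ± 0.29 (SE), which was not past the threshold (adjusted p = 0.777). Its signal was 513 on control replicate 4 and between 213 and 289 on the other controls, against 105 to 222 on the GR_KO arrays. The log2 fold changes of 1421866_at and 1453860_s_at were -0.38 and -0.32, and that of 1431378_at, below the signal filter, was -1.34. The position of each probe set relative to the deleted part of the gene was not analysed here, so a probe set outside it reports only the level of the transcript.

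**Figure D1:**
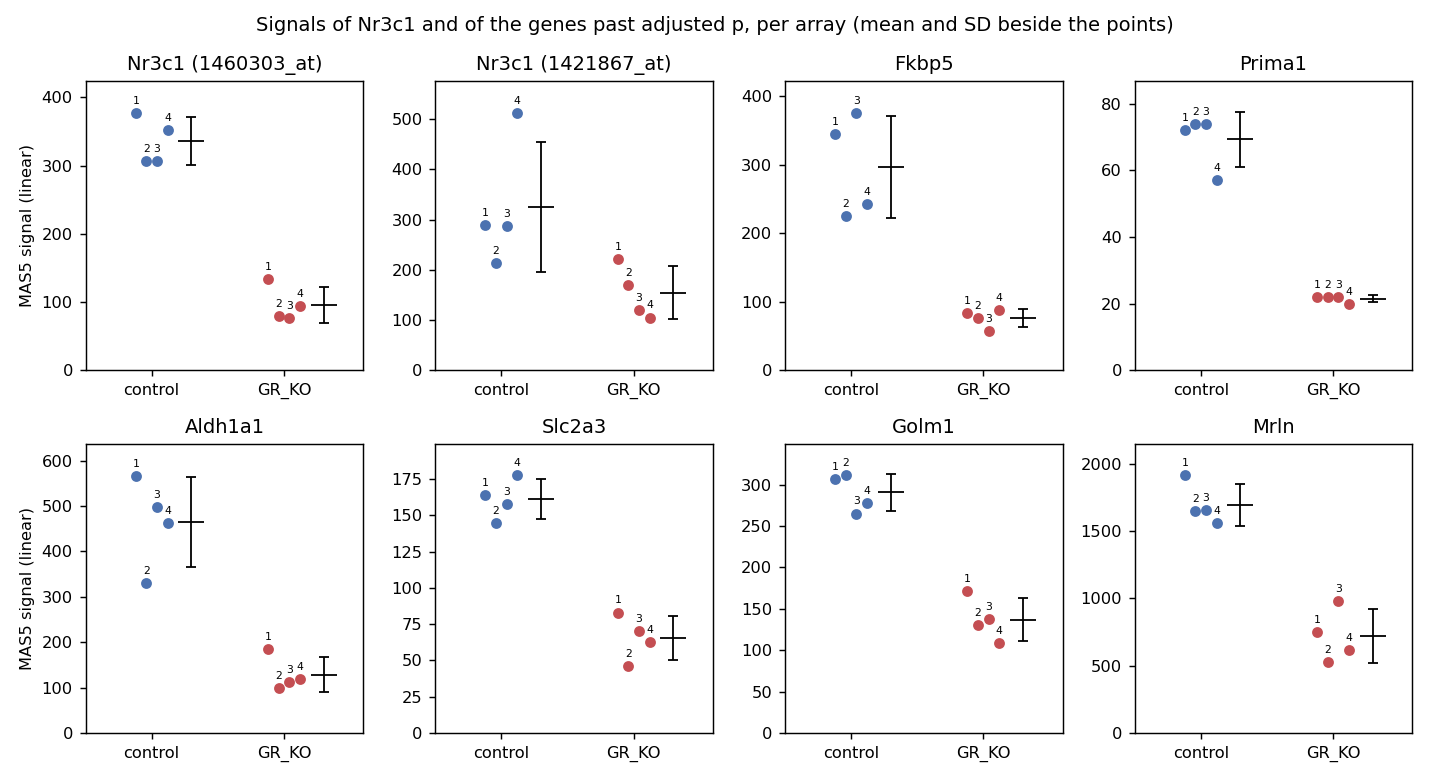
MAS5 signal (vertical axis, linear scale from 0) of 2 Nr3c1 probe sets and of the 6 genes past the threshold, for control and GR_KO muscle. Each point is 1 array with its replicate number, and the bars give mean and SD (n = 4). For all 6 genes and for Nr3c1 probe set 1460303_at the 4 GR_KO signals lie below the 4 control signals, while for 1421867_at the highest GR_KO signal, 222, lies above the lowest control signal, 213.

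In GR_KO muscle, 6 of the 11062 genes tested were lower past an adjusted p of 0.05 in limma, and 0 were higher. Fkbp5, a co-chaperone of steroid receptors, fell 3.85-fold, from a signal of 297 ± 74.4 to 76.2 ± 13.8 (mean ± SD, n = 4; log2 fold change -1.95 ± 0.21 SE, adjusted p = 0.0132). Aldh1a1, an enzyme that makes retinoic acid from retinaldehyde, fell 3.65-fold, from 464 ± 99.2 to 128 ± 37.9 (adjusted p = 0.0132). Prima1, which anchors acetylcholinesterase in the membrane, fell 3.21-fold, from 69.2 ± 8.22 to 21.5 ± 1 (adjusted p = 0.0132). Slc2a3, a glucose transporter, fell 2.51-fold from 161 ± 13.7 to 65.5 ± 15.4, and Mrln, the micropeptide that inhibits the calcium pump of the sarcoplasmic reticulum, fell 2.42-fold from 1694 ± 156 to 719 ± 199. Golm1, a Golgi membrane protein, fell 2.15-fold from 290 ± 22.7 to 137 ± 26.1. These last genes each had an adjusted p of 0.0476.

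For all 6 genes the 4 GR_KO signals lay below the 4 control signals. Further probe sets above the signal filter had log2 fold changes of -2.16 for Fkbp5, -0.89 for Prima1 and -0.68 for Slc2a3. Non-overlapping groups were seen in 285 of the 11062 genes, or 2.58%, where chance alone gives 2.86%. At an unadjusted p under 0.05 there were 512 genes, of which 262 were higher and 250 lower, where chance gives 553. As many genes passed in 2 of the 35 ways of dividing the arrays 4 against 4. The count of 6 depended on single arrays: limma called 0 genes without control replicate 1, control replicate 3, GR_KO replicate 2 or GR_KO replicate 4 (389, 510, 329 and 350 genes at an unadjusted p under 0.05), 3 without control replicate 2 and 2 without GR_KO replicate 3.

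No gene that was higher in GR_KO muscle passed the threshold. The higher genes with the smallest p-values were Rhobtb1 (log2 fold change 0.62 ± 0.12 SE, adjusted p = 0.267), Nkain1, a partner of the sodium pump (0.86 ± 0.19, adjusted p = 0.434), and Pcbd1, an enzyme of tetrahydrobiopterin recycling (1.23 ± 0.27, adjusted p = 0.458). The log2 fold changes of Dop1b, Rian and Nrep were 0.57, 1.28 and 0.58, with adjusted p-values of 0.570, 0.675 and 0.711. All but Rian had GR_KO signals above all 4 control signals. Further probe sets above the signal filter had log2 fold changes of 0.71 for Rhobtb1, 0.12 for Dop1b, 0.62 for Rian and 0.46 for Nrep. Those of Nkain1 had 0.21, 0.65 and 0.98.

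Genes that glucocorticoids are known to induce fell as a list. Of its 28 tested members, 18 had a log2 fold change below 0 and 10 above, and the mean was -0.21 (camera with the preset correlation, adjusted p = 0.00381). With an estimated correlation the list was not past the threshold (adjusted p = 0.295). The estimate was 0.00460, below the preset 0.01, so this loss did not come from a higher correlation among the members. Camera on ranks, which limits the weight of single members, did not pass the list either (adjusted p = 0.156). The median of the members was -0.19, and the largest falls were those of Arrdc2 and Fkbp5 (-1.96 and -1.95). Fkbp5 was the only member past adjusted p over all genes tested, and 5 members passed when p-values were adjusted over the list alone. These were Fkbp5, the arrestin-domain gene Arrdc2 (log2 fold change -1.96 ± 0.34 SE), the regulatory subunit of phosphoinositide 3-kinase Pik3r1 (-0.66 ± 0.17), the mTORC1 inhibitor Ddit4 (-0.75 ± 0.21) and the cell cycle inhibitor Cdkn1a (-0.76 ± 0.23). Cdkn1a was chosen after its values were seen, and their adjusted p-values over all genes, Fkbp5 aside, lay between 0.140 for Arrdc2 and 0.850 for Ddit4 and Cdkn1a. Other members of the list did not move this way: Tsc22d3, a glucocorticoid-induced leucine zipper protein, had a log2 fold change of 0.24 ± 0.13 (adjusted p = 0.880), with -0.05, 0.01 and 0.19 at its other probe sets, and the lipoprotein lipase inhibitor Angptl4 had 1.23 ± 0.45 (adjusted p = 0.880). The list scores of the 4 GR_KO arrays lay below those of all 4 controls, which gives the smallest p an exact permutation test of 4 against 4 can give, 0.0286. Without GR_KO replicate 1 the adjusted camera p was 0.0854.

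Muscle atrophy genes, ubiquitin ligases and other targets of FoxO factors among them, also fell as a list. Of 24 tested members, 18 had a log2 fold change below 0, and the mean was -0.15 (camera adjusted p = 0.0257). With an estimated correlation it was not past the threshold (adjusted p = 0.763). No member passed over all genes or when adjusted over the list alone. The members with the smallest p-values were Mt1, a metallothionein (log2 fold change -0.51), the zinc finger gene Zfand5 (-0.45), Bnip3, a mitophagy receptor (-0.26), and Foxo4 (-0.32). The atrophy ubiquitin ligases Fbxo32 and Trim63 had log2 fold changes of -0.25 ± 0.22 and -0.10 ± 0.15 (SE), with 95% intervals from -0.74 to 0.24 and from -0.44 to 0.24, and Foxo3 had -0.06 ± 0.18. Further probe sets above the signal filter had -0.48 and -0.17 for Fbxo32 and -0.13 for Foxo3. The list scores did not overlap between the groups (exact permutation p = 0.0286). The adjusted camera p was 0.219 without control replicate 1, 0.187 without GR_KO replicate 1 and 0.0599 without GR_KO replicate 4.

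Genes of glycolysis and glycogen metabolism also fell as a list. Of 22 tested members, 16 had a log2 fold change below 0, and the mean was -0.15 (camera adjusted p = 0.0257). With an estimated correlation it was not past the threshold (adjusted p = 0.880), and the exact permutation p of the list scores was 0.171. Gbe1, the glycogen branching enzyme, was 2.02-fold lower and passed when adjusted over the list alone (adjusted p = 0.0457), and no member passed over all genes. The members Pfkfb3, which makes an activator of phosphofructokinase, Ugp2, which makes UDP-glucose, and Phka1, a subunit of phosphorylase kinase, had log2 fold changes of -0.66, -0.37 and -0.26. Further probe sets above the signal filter had -0.83 for Pfkfb3, from -0.46 to -0.12 for Ugp2, and -0.69 and -0.45 for Phka1. Without control replicate 4 the mean was -0.09 and the adjusted camera p 0.186, and without GR_KO replicate 1 they were -0.09 and 0.636.

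**Figure D2:**
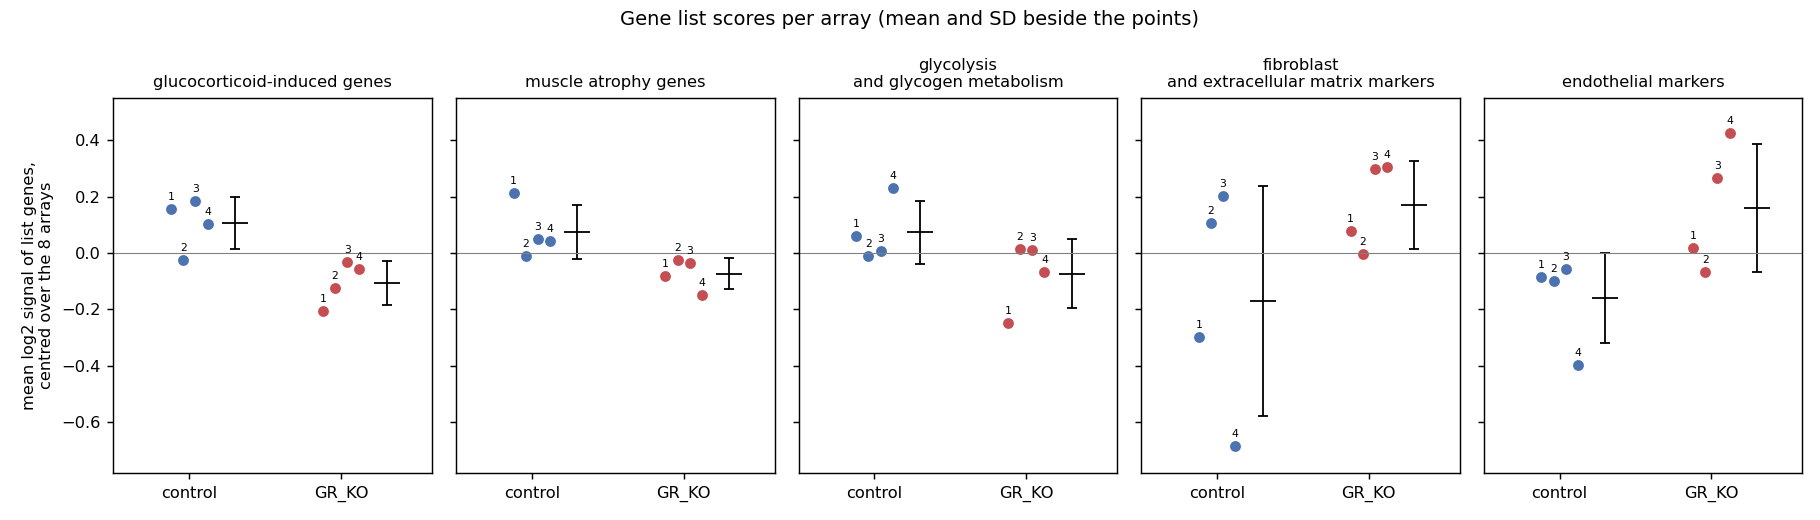
Score of the 5 gene lists past the threshold in each array: the mean log2 signal of the tested members, each gene centred over the 8 arrays (vertical axis, log2 units). Each point is 1 array with its replicate number, and the bars give mean and SD (n = 4). Control replicate 4 has the lowest score of fibroblast and extracellular matrix markers, -0.69, and of endothelial markers, -0.40.

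Markers of endothelial cells and of fibroblasts with their extracellular matrix were higher as lists in GR_KO muscle with the preset correlation. Of 18 endothelial markers, 17 had a log2 fold change above 0, and the mean was 0.32 (camera adjusted p = 1.36e-05). With an estimated correlation the list was not past the threshold (adjusted p = 0.763). The tight junction gene Cldn5 had a log2 fold change of 0.61 ± 0.20 (SE), the endothelial transcription factor Sox18 0.58 ± 0.22, the endothelial growth factor receptor Kdr 0.35 ± 0.13 and endoglin, Eng, 0.39 ± 0.17. Of 24 fibroblast and matrix markers, 21 had a log2 fold change above 0, and the mean was 0.34 (camera adjusted p = 0.000159). With an estimated correlation this list was not past it either (adjusted p = 0.880). Among these the collagen genes Col1a2, Col3a1 and Col6a2 had log2 fold changes of 0.74, 0.62 and 0.81, and Fstl1 had 0.57. Further probe sets above the signal filter had 0.57 and 0.38 for Col1a2, 0.16 for Col3a1, 0.65 for Col6a2 and -0.05 for Fstl1. No marker of either list passed over all genes or adjusted over the list alone. The exact permutation p-values of the list scores were 0.0571 and 0.229. Control replicate 4, whose spike-in signals also stood apart, had the lowest score of both lists. Without it the mean shifts were 0.24 for endothelial and 0.17 for fibroblast and matrix markers.

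Other cell type markers did not pass camera with the preset correlation. Schwann cell and nerve markers had a mean log2 fold change of 0.25 (adjusted p = 0.303), erythrocyte markers 0.10 (adjusted p = 0.776), smooth muscle and pericyte markers 0.08 (adjusted p = 0.776), adipocyte markers -0.01 (adjusted p = 0.965), and satellite cell markers -0.04 (adjusted p = 0.835). With single arrays left out, the mean ranged from 0.12 to 0.43 for Schwann cell and nerve markers, from 0.04 to 0.22 for erythrocyte markers and from 0.01 to 0.13 for smooth muscle and pericyte markers. Macrophage and leukocyte markers had a mean of -0.23 (adjusted p = 0.499), with an SD of the list score of 0.67 among control and 0.58 among GR_KO arrays, and its mean shift lay between -0.53 without control replicate 1 and 0.00426 without control replicate 4. It was -0.42 without GR_KO replicate 1, -0.37 without GR_KO replicate 2, -0.08 without GR_KO replicate 3 and -0.05 without GR_KO replicate 4.

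In lists that did not pass as a whole, 8 genes were past the threshold when adjusted over the list alone, and 0 of them over all genes. Adjustment over a list alone does not cover the number of lists searched, so chance could give some such genes. Ddit4 and Pik3r1, 2 of the 8, had also passed in the glucocorticoid-induced list. Rab7, a GTPase of late endosomes and lysosomes, was 1.79-fold lower (list alone, adjusted p = 0.00155; over all genes, adjusted p = 0.0822) in the autophagy and lysosome list (camera adjusted p = 0.218). The amino acid transporter Slc43a1 was 1.75-fold lower in the amino acid and polyamine list (camera adjusted p = 0.776). Chac1, an enzyme of glutathione breakdown, was 2.18-fold lower in the unfolded protein and integrated stress response list (camera adjusted p = 0.776). Bhlhe40, a repressor of the circadian clock, was 1.62-fold lower in the clock list (camera adjusted p = 0.0931). Among negative regulators of insulin, IGF-1 and mTOR signalling (camera adjusted p = 0.527), Ddit4, Pik3r1 and Depp1 were 1.68-, 1.58- and 1.69-fold lower, while Deptor, an inhibitor of mTOR, was 1.44-fold higher at its brightest probe set. The other Deptor probe sets above the signal filter had log2 fold changes of 0.50, 0.07, -0.07 and -0.19.

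The remaining lists, those of contractile genes among them, did not pass the camera test. The mean log2 fold changes were 0.04 for slow-fibre contractile genes (adjusted p = 0.965), -0.10 for fast-fibre contractile genes (adjusted p = 0.336), 0.08 for excitation-contraction coupling and calcium handling (adjusted p = 0.499), 0.03 for oxidative phosphorylation (adjusted p = 0.776), 0.07 for fatty acid uptake and oxidation (adjusted p = 0.919) and -0.02 for cholesterol biosynthesis and lipogenesis (adjusted p = 0.794). Control replicate 4 had centred scores of -0.95 for slow-fibre and 0.61 for fast-fibre genes. Without it the mean shifts were -0.27 for slow-fibre and 0.08 for fast-fibre genes, and the sign also changed without control replicate 2 for slow-fibre genes (-0.03) and without GR_KO replicate 1 for fast-fibre genes (0.02). Insulin, IGF-1 and mTOR signalling components had 0.07 (adjusted p = 0.776), proteasome subunits 0.03 (adjusted p = 0.776) and cytosolic ribosomal proteins 0.06 (adjusted p = 0.677). Heat shock genes and chaperones had 0.01 (adjusted p = 0.965), and nuclear receptors with metabolic coactivators -0.01 (adjusted p = 0.965). Immediate early genes had -0.05 (adjusted p = 0.267), interferon-stimulated genes -0.08 (adjusted p = 0.750), inflammatory cytokines and NF-kB targets 0.04 (adjusted p = 0.794), denervation and neuromuscular junction genes 0.09 (adjusted p = 0.794), myogenic regulators 0.02 (adjusted p = 0.965) and cell cycle genes -0.02 (adjusted p = 0.965). Of the 28 lists not past the threshold, 26 had a mean shift that moved by over 1.5 times or changed sign when some single array was left out, all but autophagy and lysosome and negative regulators of insulin, IGF-1 and mTOR signalling. The shift of denervation and neuromuscular junction genes was 0.00139 without control replicate 4. The sign changed for 16 lists. Without control replicate 4 it did so for 8 lists: slow-fibre, fast-fibre, proteasome, immediate early, heat shock, interferon-stimulated and myogenic genes, and macrophage and leukocyte markers. No list past the threshold changed sign without any single array, but 2 of the 5 moved by over 1.5 times. Fibroblast and matrix markers went from 0.34 to 0.17 without control replicate 4. Glycolysis and glycogen metabolism went from -0.15 to -0.09 without GR_KO replicate 1. These 5 lists had been called for their shift on the same arrays, which by itself makes a change of sign less likely.

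Of the 33 lists, 5 passed camera with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.295. The estimate was far above the preset 0.01 for fibroblast and matrix (0.461), endothelial (0.315) and glycolysis and glycogen lists (0.171). It was 0.0520 for muscle atrophy genes and 0.00460 for glucocorticoid-induced genes. The directional fry test passed 0 lists, and its mixed form passed the glucocorticoid-induced list alone (adjusted p = 6.72e-06). The median and mean of the members differed in sign for cholesterol biosynthesis and lipogenesis, nuclear receptors, satellite cell markers and cell cycle genes. The direction in camera was opposite to the mean for slow-fibre contractile genes, myogenic regulators and nuclear receptors. As many as 5 lists passed in 26 of the 35 ways of dividing the arrays 4 against 4.

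**Figure D3:**
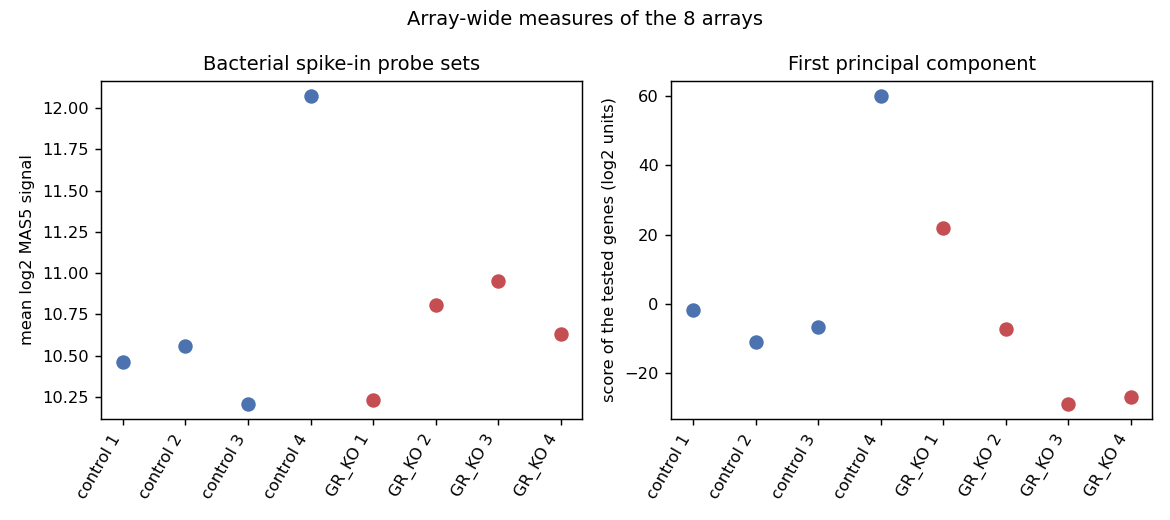
Mean log2 signal of 8 bacterial spike-in probe sets (left) and score on the first principal component of the tested genes (right) for each of the 8 arrays, control in blue and GR_KO in red. Control replicate 4 has the highest value in both panels, 12.07 and 59.8.

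The spike-in signal of control replicate 4 was 3.16-fold that of the other controls. Its 3'/5' signal ratio for Gapdh was 1.20 against 0.804 to 0.873 in the other controls. That for Actb did not stand apart, at 1.73 against 0.991 to 1.59 in the other controls and 1.07 to 1.84 on GR_KO arrays. Its median correlation with the other arrays was 0.925, where the other arrays had 0.964 to 0.972. The first principal component held 45.7% of the variance. Its score was 59.8 on control replicate 4 and 22.0 on GR_KO replicate 1, and below 0 on the remaining arrays. None of 8 array-wide measures passed an exact permutation test between the groups (p from 0.457 to 0.914, n = 4 per group). Without control replicate 4, 4 genes and 7 lists passed the threshold, and without GR_KO replicate 1, 5 genes and 4 lists.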

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

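The tests of the signal level of control replicate 4 and of the myofibre share were chosen after the results were seen. The other tests in this part were written down before their values were known. Among 120 sets of 4 arrays (47 genes, 5 list scores and 8 array-wide measures, each in both groups), 10 held an array whose gap to its nearest neighbour, relative to the range of the set, exceeded Dixon's 95% critical value. Chance gives such a gap in about 1 in 20 sets, or 6 here.

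Of the 10, 4 were on control replicate 4. These were its median log2 signal of 7.11 against 6.97 to 6.99 in the other controls, its first principal component score of 59.8, its endothelial marker score of -0.40 against -0.10 to -0.06, and its Prima1 signal of 57 against 72 to 74. The other sets were single gene signals. Prima1 was 20 on GR_KO replicate 4 and 22 on the other GR_KO arrays. Rhobtb1 was 243 on control replicate 1 against 280 to 281. Rian was 60 on control replicate 2 against 27 to 29. Nrep was 4182 on GR_KO replicate 3 against 3534 to 3567. Pik3r1 was 562 on control replicate 1 against 447 to 457. Gbe1 was 25 on GR_KO replicate 3 against 45 to 48.

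The first pattern weighed was the set of 6 genes that were lower in GR_KO muscle. Without control replicate 4 their median log2 fold change was -1.54, against -1.50 with it, so the size of that median did not rest on this array. Of the 6 genes, 3 still passed the threshold without it. The genes had been picked on the same arrays for a difference large against the spread within groups. That choice by itself largely keeps their fold changes when a single array is left out. The comparison therefore cannot decide whether the signal level of control replicate 4 was the source. None of the 6 genes, 0, lay on the chromosome of Nr3c1, which argues against DNA around the Nr3c1 locus carried with the knockout allele. The real division of the arrays gave 6 genes, and the highest of the others gave 63, so that 2 of the 35 divisions gave at least as many and chance cannot be excluded for the count. The division with 63 genes set control replicates 1, 3 and 4 and GR_KO replicate 1 against the rest, which points to a structure of the samples that the groups do not follow, and only 2 of the other 34 divisions gave any gene. The loss of the receptor, which the design names, remains open as the biological explanation.

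For the gene lists past the threshold, no technical source common to all was weighed. With 5 lists in the real division and 11 in the highest of the others, 26 of the 35 divisions gave as many, so chance cannot be excluded for the count of lists. For single lists the number of divisions with a camera p as small was 1 for glucocorticoid-induced genes (0.000346, against 0.000425 as the smallest of the others), a share under 0.05. That is the smallest share the design can give and the list is 1 of 33, and its exact permutation test adjusted over the lists did not pass (adjusted p = 0.471), so chance is not excluded over the lists tested. It was 3 for endothelial markers, 4 for muscle atrophy genes, 9 for fibroblast and matrix markers and 11 for glycolysis and glycogen metabolism, where chance cannot be excluded. The unadjusted p in the real division and the smallest of the others were 4.13e-07 and 1.64e-09, 0.00389 and 0.00140, 9.62e-06 and 3.43e-11, and 0.00335 and 5.49e-05 in that order.

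The second pattern was the higher endothelial and matrix markers. Without control replicate 4 the mean log2 shift of fibroblast and matrix markers was 0.17 instead of 0.34 (exact permutation p = 0.429 over the remaining arrays). That of endothelial markers was 0.24 instead of 0.32 (exact permutation p = 0.200). As the whole source the array would bring these shifts to about 0. Both were smaller, which leaving out the control with the lowest score of both lists brings about by itself. Camera with the preset correlation still passed both without it (adjusted p = 0.0198 for fibroblast and matrix and 0.000674 for endothelial markers). In the exact test what remains of both lies within the spread of the arrays, which leaves the question open. A lower share of myofibre RNA could raise markers of all other cell types alike. Endothelial markers shifted by 0.55 more than macrophage and leukocyte markers (exact permutation p = 0.400), and by 0.24 without control replicate 4. Of 7 such comparisons the smallest p was that against satellite cell markers (0.36, exact permutation p = 0.0286, adjusted p = 0.200), so with the spread of these scores a lower myofibre share cannot be told apart from a change in the endothelial cells. An effect of the receptor loss on these cells was not tested.

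The third pattern was control replicate 4 itself. Its 8 spike-in probe sets exceeded the other controls by a median log2 of 1.66. The 6081 sample probe sets of the same brightness had a median excess of -0.22, and 0.460% of them reached the median of the spike-ins, which argues against a brightness-dependent scale of the whole array as the source of the spike-in excess. Above the range of the spike-ins, 77 sample probe sets with a mean log2 signal over 13 had a median excess of 0.66, and 2 of them reached the lowest spike-in excess, so a smaller shift of the brightest probe sets remains open. Of the 6081 probe sets in the brightness range of the spike-ins, 99.2% lay below the lowest spike-in excess of 1.40. This was the outcome predicted for less sample cRNA relative to the spike-ins on that array. As the arrays had been scaled to a common mean, it largely restates the spike-in excess and does not decide its source. No biological explanation was tested for this array.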

How the results depend on the processing

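All alternatives but the spike-in covariate were chosen before the data were examined. The 6 genes had log2 fold changes below 0 in every setting in which they were tested as genes. They had been picked on these arrays for a large difference, which by itself largely keeps their sign. The number of genes higher past the threshold in limma was 0 in all settings (262 higher at an unadjusted p under 0.05 in the reported fit). The number of genes past the threshold, all lower, was 0 with no filter on dim probe sets (857 at an unadjusted p under 0.05), where more genes entered the adjustment. It was 1 with the mean of a gene's probe sets, 2 without the trend, 10 with array weights and 3 with the spike-in covariate. It ranged from 0 to 5 when each array was left out in turn. With quantile normalization it was 9, with median centring 4. Where the cause is not named, it was not tested. With every probe set above the signal filter tested, 22518 in all, 5 probe sets of 4 genes passed, and 0 of them had no single gene. Nr3c1 probe sets 1460303_at and 1457635_s_at were among these, so several of the 6 genes had no probe set past the threshold there.

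The labels do not say whether the replicate numbers pair the samples, and the arrays showed no sign of it. The correlations of same-numbered arrays' deviations were -0.19, 0.18, 0.11 and -0.39. Of 4 controls, 0 correlated best with the array of its own number. So few correlations cannot exclude a pairing. With the number as a block in the fit (replicate block) 1 gene, Aldh1a1, and 5 lists passed. The block was run for the gene test and for camera with the preset correlation alone. There no call changed beyond the genes lost.

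The Nr3c1 log2 fold change was below 0 with all probe sets and settings. It was past the threshold with probe sets 1457635_s_at (-1.96) and 1460303_at (-1.84) alone, tested among the probe sets above the signal filter. Of the named genes not past the threshold, Foxo3 changed sign without control replicate 1 (0.0860) and without GR_KO replicate 2 (0.00588), and Trim63 without control replicate 1 (0.00427). Over the arrays left out, the log2 fold change ranged from -0.20 to 0.09 for Foxo3 and from -0.21 to 0.00427 for Trim63. Single gene values changed sign in 3 cases, passed the threshold newly in 3, lost it in 61 and stayed on their side in 848. Most of the 848 belonged to genes not past the threshold in the reported fit, and all 61 losses to genes past it there. Of those, Fkbp5 and Aldh1a1 each passed in 13 of 20 alternatives and Prima1 in 10 of 19. Slc2a3 passed in 8 of 20, and Golm1 and Mrln each in 7 of 20.

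The number of lists past the threshold was 0 with an estimated correlation, 3 with rank-based camera, 0 with directional fry and 1 with mixed fry, and ranged from 4 to 8 when each array was left out. Adjusted p-values with an estimated correlation, rank-based camera and directional fry were 0.295, 0.156 and 0.103 for glucocorticoid-induced genes. For glycolysis and glycogen metabolism they were 0.880, 0.0930 and 0.826, with 0.430 in mixed fry, 0.0545 with the filter at the 70th percentile and 0.106 with the spike-in covariate. For muscle atrophy genes they were 0.763 with an estimated correlation, 0.691 in directional and 0.743 in mixed fry. For fibroblast and matrix markers these were 0.880, 0.826 and 0.648, and for endothelial markers 0.763, 0.691 and 0.345. The 3 lists past the threshold in rank-based camera were muscle atrophy genes (adjusted p = 0.0271), fibroblast and matrix markers (8.73e-05) and endothelial markers (2.49e-05). With each array left out in turn, the adjusted camera p with the preset correlation ranged from 0.000545 to 0.0854 for glucocorticoid-induced genes. It ranged from 0.00145 to 0.219 for muscle atrophy genes and from 0.000781 to 0.636 for glycolysis and glycogen metabolism. For fibroblast and matrix markers it ranged from 3.30e-07 to 0.0198, and for endothelial markers from 2.32e-08 to 0.00199, past the threshold each time. In these fits fewer samples entered the test.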

Other observations

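The tests of the Dlk1-Dio3 RNAs and of the hour of collection were chosen after the results were seen. Rian, an imprinted non-coding RNA of the Dlk1-Dio3 region, was among the higher genes with the smallest p, and Meg3 and Mirg are transcribed from the same region. The 2 Rian probe sets above the signal filter had a mean log2 shift of 0.95, which restates that choice. The 8 probe sets of Meg3 had 0.25 (exact permutation p = 0.257) and the 2 of Mirg 0.18 (exact permutation p = 0.514). A common shift of the region's non-coding RNAs was a hypothesis from these data. Over the 10 probe sets of Meg3 and Mirg, without Rian, the shift was 0.24 (exact permutation p = 0.200), which did not pass and neither shows nor excludes a common shift.

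Of 17 tested clock genes, 13 had a log2 fold change below 0 and 4 above, and the list did not pass camera (adjusted p = 0.0931). Among those with the smallest p-values, Bhlhe40 and Cry2 had log2 fold changes of -0.69 and -0.41, and Per2 and Hlf had 0.62 and 0.47, none of them past the threshold over all genes and only Bhlhe40 adjusted over the list alone. A different hour of tissue collection could move the clock outputs Dbp, Tef, Nr1d1, Nr1d2 and Ciart against the activators Arntl (Bmal1) and Clock. Npas2, a further activator meant for this test, was below the signal filter and did not enter it. The difference of the shifts was -0.13 (exact permutation p = 0.629), so these arrays neither show such a difference in hour nor exclude it.

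Sex-linked transcripts were measured as a check of the samples. The brightest Y-linked probe set, of Eif2s3y, had signals from 49 to 265, and the brightest Xist probe set had signals from 18 to 31 over the 8 arrays. The groups overlapped for both, and control replicate 4 had the highest signal of each, 265 and 31. Xist lay near the signal filter of 19.4 on all 8 arrays, so these transcripts gave no sign that sex differed between the groups.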
